A study of Rattus norvegicus with 8 samples.

How the data were processed

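The series holds 8 single-colour arrays of total RNA from rat liver, 1 for each sample: 5 samples from high-fat diet and 3 from standard chow. The labels do not say that each sample came from a different animal. In the names of the high-fat samples replicates 1 and 2 share a leading number, as do replicates 3 and 4, and the labels do not give its meaning. Groups and replicate numbers were taken from the sample titles, and diet length, age and sex from the labels. The submitters' processing notes name Agilent Feature Extraction 11.0.1.1 as the software that read the scans. Per the file headers, the scanner files hold the processed signal in intensity units, with background subtracted and trends removed within the array but no scaling between arrays. Per the file headers they also hold the median signal and the median local background as raw intensity, and other columns that mark each spot with 0 or 1 as above background, saturated or an outlier. The authors' value table holds log2 values, with 1 value for each probe; the 75th percentiles of its 8 columns were equal (largest gap 0), the medians of the probes that were not controls ran from 6.423 to 6.424, and its values correlated with the log2 processed signal of the same array at 0.995 to 0.999, as in quantile normalization. How the authors made that table is not stated in the labels.

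Each array had 44254 spots, of which 42877 were not controls and held 30367 probes; 1390 probes had 10 spots. Spots marked as outliers were left out (331 to 550 for each array), and 0 spots were saturated. Spots of a probe were averaged as log2 of the processed signal, and the 75th percentile of each array was subtracted. A probe was kept if at least 0.5 of its spots were well above background on at least 3 of the 8 arrays, counted without regard to diet. Probes were named through the RefSeq accessions printed for the array, matched to a table of rat genes on the GRCr8 assembly: 18005 probes received 15168 gene symbols. Genomic positions are not given, since the array design and that table use different assemblies. For each gene the probe with the highest mean over all 8 arrays was used, which left 22863 features, 13336 of them with a symbol. Features without a symbol were tested under the name the array design gives. Principal components and list tests used the 22723 features with a value on every array.

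Signal over background sets the depth of an array: the share of probes above background was 66.9% to 92.7%. The lowest signal above background lay at −6.39 to −4.55 on the log2 scale relative to the 75th percentile of its array, and lay higher on each chow array than on each high-fat array. Where a gene was above background on no chow array, its fold is given as a lower bound, with each chow value raised to the lowest signal above background of that array. That level belongs to the dimmest probe above background on the array, and the limit of another probe can lie higher. The bound compares group means and carries no error, so each "at least" holds only against that level. The number of arrays limits the precision. Slide and scan day were read from the scanner files. All arrays were compared with each other for identical values, and 0 pairs were identical. The spike-in slope was 0 on every array, so no spike-in calibration was used.

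High-fat diet was compared with chow by a linear model with moderated variances (limma 3.58.1, lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05, and a further threshold of 2-fold. Gene lists (46 lists with at least 5 measured genes, covering lipid and glucose metabolism, other liver functions, and markers of cell types and neighbouring tissues) were tested with camera of limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data and with fry, each adjusted over the 46 lists. For every list the count of genes passing was also taken with p adjusted over the list alone. Many genes stand in more than 1 list. Values with 1 number per array were compared with an exact permutation test (two-sided, all 56 splits of 8 arrays into 5 and 3). The design, the gene lists, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined.

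Named genes were chosen by rule. Among features that passed, did not overlap between diets, had a symbol and were well above background on every array of at least 1 diet, the 8 with the largest increase and the 8 with the largest decrease were taken. From each list the 3 genes with the smallest adjusted p under 0.05 were added, and 19 genes of lipid and glucose metabolism were named whatever their p; Srebf1 and Acaca among them were not analysed here. A few genes chosen by these rules are not reported here. A further 11 genes, given among the other observations, were chosen after their values were seen.

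The method was tested on simulated data: noise with the spread of these arrays, 22723 genes and 50 genes changed at each size. It recovered 2% of the genes changed 1.5-fold, 22% of those changed 2-fold, 72% of those changed 4-fold and 92% of those changed 8-fold, and 6 of the 100 genes it called were unchanged ones. On simulated lists, camera found the shifted list and also called an unshifted list. The simulated noise was independent between genes and arrays and held no slide effect, so these rates need not hold for the real arrays. Each alternative changed 1 choice, or a background and a scaling together: scaling to the median, quantile normalization, a normexp background (offset 50) with percentile or quantile scaling, the authors' table, no filter or a filter on all 8 arrays, the mean over the probes of a gene, a variance trend with robust estimation, array weights, slide or scan day as a block, the number in the high-fat samples' own names as a random block, a replicate block on the 6 arrays numbered 1 to 3, the same arrays without it, an unadjusted threshold, and each array left out in turn. The normexp alternatives used the median spot signal in place of the mean signal that had been chosen, since the columns read here hold the median. Cyclic loess normalization, the arrays of scan day 1 alone, and the high-fat arrays of slide 1 alone were added after seeing the data. Slide entered as a random block because no slide held both diets, so a feature that passes with that block is not thereby free of a slide effect. Tools were R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.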

Results

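Gene expression was measured in 8 liver samples from male rats aged 22 weeks, with 1 single-colour array for each sample. After 14 weeks on the diets, 5 samples came from high-fat diet, and the labels give their disease state as NAFLD (non-alcoholic fatty liver disease). The other 3 samples came from standard chow and served as controls. The series title places the question in glucose and lipid metabolism: which genes of these pathways differ between fatty and normal liver. Each value is the log2 signal of a probe relative to the 75th percentile of its array. The share of probes well above background was 79.0%, 81.2%, 92.7%, 79.4% and 87.1% on high-fat arrays 1 to 5, and 71.7%, 68.7% and 66.9% on chow arrays 1 to 3. The number of arrays limits the precision of every comparison. The labels do not state more than separate samples, so the p-values measure the spread between these samples.

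The arrays fell into 3 groups in the principal components of 22723 features, 1 for each slide. Slide 1, scanned on day 2, held high-fat arrays 1 and 4; slide 2, scanned on day 1, held high-fat arrays 2, 3 and 5; and slide 3, also scanned on day 1, held all 3 chow arrays. The first component carried 37.8% of the variance and set the high-fat arrays of slide 1 (scores −63.1 and −53.3) apart from those of slide 2 (36.2, 69.3 and 54.7), with the chow arrays between them (−19.9 to −6.59). The second component carried 27.3% and set the high-fat arrays (−43.8 to −16.5) apart from the chow arrays (42.2 to 54.6). Pearson correlations across genes, which are not independent replicates, ran from 0.987 to 0.989 between high-fat arrays of the same slide and from 0.971 to 0.979 between high-fat arrays of different slides. They ran from 0.982 to 0.984 between chow arrays and from 0.967 to 0.978 between high-fat and chow arrays.

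**Figure D1:**
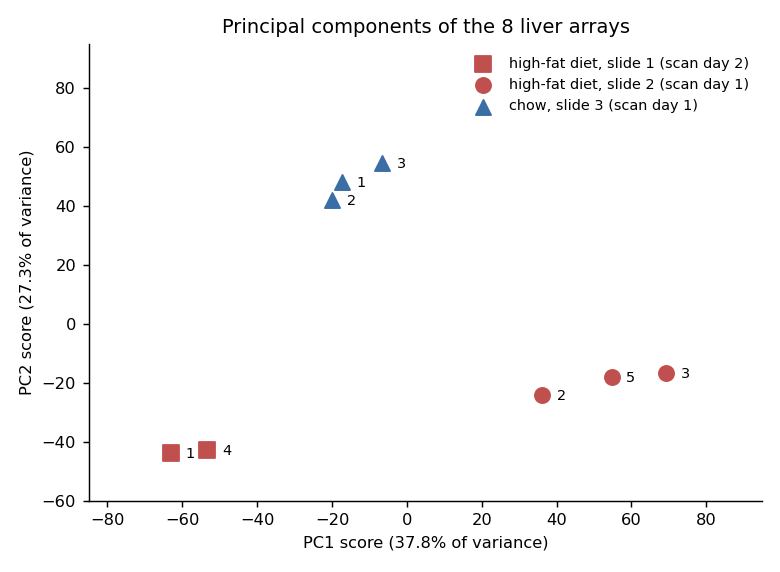
Scores of the 8 liver arrays on the first (x axis, 37.8% of variance) and second (y axis, 27.3% of variance) principal components, in score units; colour gives the diet, shape the slide, and the number the replicate. The high-fat arrays of slide 1 lie at −63.1 and −53.3 on the first component and those of slide 2 at 36.2 to 69.3, while all 3 chow arrays lie at 42.2 to 54.6 on the second.

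The high-fat arrays were brighter. Their 75th percentile signal averaged 856 ± 134 intensity units (SD, n = 5), against 379 ± 156 (SD, n = 3) on the chow arrays (exact permutation p = 0.0179, two-sided, the smallest that 56 splits allow; 0.0357 after Benjamini-Hochberg adjustment over 6 array measures). The share of probes above background averaged 83.9% ± 5.91 (SD, n = 5) against 69.1% ± 2.43 (SD, n = 3), with the same exact p of 0.0179 and adjusted value of 0.0357. The median signal, 125 ± 39.0 (SD, n = 5) against 50.6 ± 19.0 (SD, n = 3), gave an exact permutation p of 0.0357, which the adjustment raised to 0.0536. The E1A control probes, which have no rat target, averaged −6.58 ± 0.47 (SD, n = 5) relative to the 75th percentile on the high-fat arrays and −6.17 ± 0.21 (SD, n = 3) on the chow arrays (exact permutation p = 0.196, adjusted 0.236). The negative control probes averaged −8.17 ± 0.24 (SD, n = 5) and −6.88 ± 0.22 (SD, n = 3) on the same scale (exact permutation p = 0.0179, adjusted 0.0357). The median signal relative to the 75th percentile differed by 0.08 (exact permutation p = 0.625).

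On high-fat diet, 3 of 28 measured genes of amino acid breakdown, 2 of 14 in the list of de novo lipogenesis (Me1 and Acacb) and the insulin receptor substrate Irs3 were lower. A larger number of features were higher, and the fatty acid synthase Fasn did not pass (limma adjusted p = 0.973). Among the genes that fell, Irs3, which encodes a docking protein of the insulin receptor in rodents, averaged −4.44 ± 0.28 (SD, n = 5) on high-fat diet and −2.32 ± 1.03 (SD, n = 3) on chow, 4.33-fold lower (log2 fold change −2.12 ± 0.41 SE, limma adjusted p = 0.0289). Me1, the cytosolic malic enzyme that supplies NADPH for fatty acid synthesis, was 2.07-fold lower (log2 fold change −1.05 ± 0.20 SE, adjusted p = 0.0281). Acacb, the mitochondrial acetyl-CoA carboxylase, was 1.97-fold lower (−0.98 ± 0.21 SE, adjusted p = 0.0405), a call lost when any 1 of the 8 arrays was left out. Among the genes that rose, Id3, an inhibitor of DNA binding by basic helix-loop-helix factors, was 8.07-fold higher (log2 fold change 3.01 ± 0.25 SE, adjusted p = 0.001). Hsd3b7, an enzyme of bile acid synthesis, was 3.24-fold higher (1.70 ± 0.29 SE, adjusted p = 0.0189). With single arrays left out, Id3 passed in 8 of 8 fits, Hsd3b7 in 6, and Irs3 and Me1 in 4. Of these 5 genes Id3 alone passed with a normexp background (the others had an adjusted p from 0.0628 to 0.114) and with slide as a random block. In total 815 of 22863 tested features passed an adjusted p of 0.05, 703 of them higher and 112 lower on high-fat diet; 624 of them differed at least 2-fold (598 higher, 26 lower). The balance of directions changed with the processing: without a filter on dim probes 699 were higher and 396 lower (600 and 308 at 2-fold), with array weights 2195 and 1579, and with a normexp background and quantile normalization 1035 and 1075. Of the 13336 tested features with a gene symbol, 249 passed (172 higher, 77 lower). The 2 diets did not overlap in any of the 815, but a threshold on p itself selects for that. They did not overlap in 3907 features (17.1% of those tested, against 3.57% by chance for arrays taken without regard to slide). No chow array shared a slide with a high-fat array, so slide and diet cannot be separated. With slide as a random block 84 features passed, all higher. In 2 alternatives chosen after seeing the data, the arrays of scan day 1 alone gave 2904 (2521 higher, 383 lower) and the high-fat arrays of slide 1 alone gave 1979 (998 higher, 981 lower). Leaving out chow array 1, 2 or 3 or high-fat array 2 lowered the count to 374, 440, 432 or 455.

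The 8 largest increases among genes chosen by the rule for named genes were in Gclm, Brd1, Oxnad1, Ltb4r2, Msx3, Id3, Nabp1 and Arvcf. Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, was at least 12.9-fold higher (adjusted p = 0.000616). It was above background on all 5 high-fat arrays and on 0 chow arrays. Its fold is thus a bound on the processed signal that holds only against the lowest signal above background of each chow array. On the same terms Ltb4r2, a leukotriene receptor, was at least 3.13-fold higher (adjusted p = 0.00323), Oxnad1 at least 3.04-fold (0.0391), Brd1, a bromodomain protein of histone acetyltransferase complexes, at least 2.89-fold (0.0107), Arvcf, a catenin of cell junctions, at least 2.45-fold (0.00323), Nabp1, a protein that binds single-stranded DNA, at least 2.43-fold (0.0141), and Msx3, a homeobox factor, at least 2.38-fold (0.00323). Id3 was above background on all 8 arrays. Of the 815 features, 276 were not above background on any chow array, and all 276 were higher on high-fat diet. The filter favours that direction: such a probe was kept only if it was above background on at least 3 of the 5 high-fat arrays, which were brighter. In the reverse case a probe had to be above background on all 3 chow arrays, and 0 of the 815 features were of that kind. Among features above background on all 8 arrays, 443 passed, 333 higher and 110 lower. Within the high-fat group Gclm, Brd1, Oxnad1 and Nabp1 were higher on slide 1 than on slide 2 by 1.38, 1.56, 1.85 and 1.36 on the log2 scale. With a normexp background model, which moved the median of all features to −0.29, 1 of these 8 genes passed, Id3, at 1.43 (adjusted p = 0.0254). Gclm was 1.77 (adjusted p = 0.0727), Oxnad1 0.42 (0.532), Msx3 0.17 (0.754), and Nabp1 and Arvcf 0.16 (0.77 and 0.713), below the bounds given above. Brd1 and Ltb4r2 turned to −0.20 and −0.03 (adjusted p = 0.663 and 0.954), or 0.09 and 0.26 relative to that median. With slide as a random block Gclm and Id3 passed. With single arrays left out, Brd1 and Nabp1 passed in 6 of 8 fits, Oxnad1 in 2, and the other 5 in 8.

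**Figure D2:**
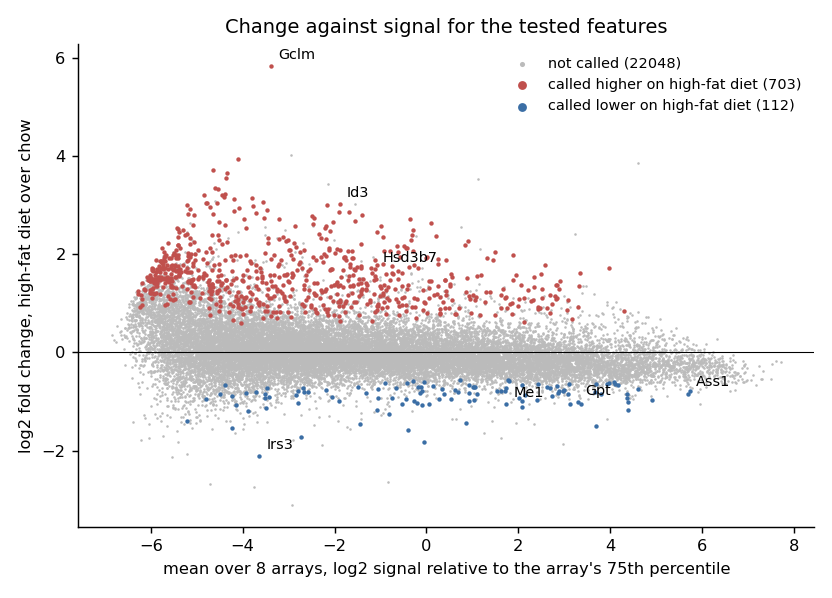
Log2 fold change of each tested feature, high-fat diet over chow (y axis), against its mean log2 signal relative to the 75th percentile over 8 arrays (x axis); red points passed an adjusted p of 0.05 higher (703), blue points lower (112), grey points did not pass. The dimmest of 10 equal bins holds 154 of the higher features and has a median of 0.51, and the brightest holds 8 and has a median of −0.24.

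The change depended on brightness. In 10 bins of equal size the median log2 fold change ran from 0.51 in the dimmest bin to −0.24 in the brightest, with −0.01 over all features. Features called higher were most frequent in the dimmest bin (154 of 2287) and least frequent in the brightest (8 of 2287), while features called lower numbered 1 and 23 in the same bins.

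Among the largest decreases of the named genes were those in Irs3, Tmem30b, Fam13a, Tjp3, Prim2, Neurl3 and Tmem116, all above background on all 8 arrays. Prim2, the large subunit of DNA primase, had the smallest spread: −1.28 ± 0.11 (SD, n = 5) on high-fat diet against −0.04 ± 0.11 (SD, n = 3) on chow, 2.36-fold lower (adjusted p = 0.00224). Tmem30b, a subunit of phospholipid flippases, was 2.98-fold lower (adjusted p = 0.0364), Fam13a, a protein with a GTPase-activating domain, 2.89-fold (0.0437), and Tjp3, a scaffold of tight junctions, 2.71-fold (0.0215). Neurl3, a ubiquitin ligase, was 2.24-fold lower (adjusted p = 0.0365) and Tmem116 was 2.20-fold lower (0.0391). A different probe of the same gene showed 89.7% of the log2 change for Tmem116 and 17.7% for Tmem30b. With single arrays left out, Prim2 passed in 8 of 8 fits, Tjp3 in 6, Irs3 in 4, Tmem30b in 2, and Fam13a, Neurl3 and Tmem116 in 1. Tmem30b, Tjp3 and Prim2 passed with a normexp background, and the other 4 did not (adjusted p from 0.108 to 0.177). With slide as a random block 0 of these 7 genes passed.

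**Figure D3:**
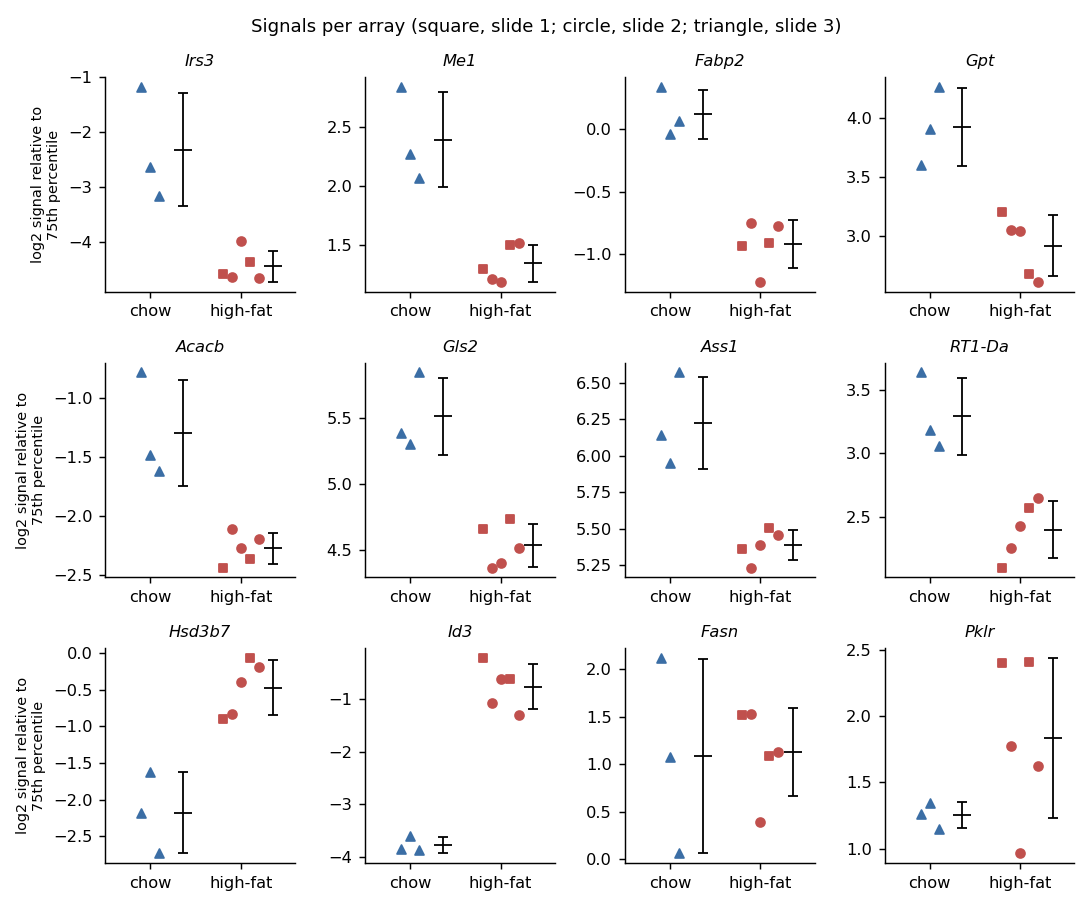
Log2 signal relative to the 75th percentile (y axis, with its own range in each panel) of 12 genes on each array, for chow (n = 3) and high-fat diet (n = 5); squares, circles and triangles mark slides 1, 2 and 3, and bars give the mean and SD. In the 10 genes that passed, such as Irs3 (log2 fold change −2.12) and Id3 (3.01), no high-fat array overlaps a chow array, which the threshold on p selects for. Fasn (adjusted p = 0.973) and Pklr (0.357) did not pass.

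Genes of the de novo lipogenesis list were lower as a group on high-fat diet with 75th percentile scaling of the processed signal. The list's mean on each array, taken relative to each gene's mean over all arrays, overlapped between diets. It was 0.82, 0.13 and −0.13 on chow arrays 1 to 3 and ran from −0.54 to 0.01 on the high-fat arrays. Of 14 measured genes of de novo lipogenesis, 2 fell (Me1 and Acacb), 0 rose, and 4 fell when p was adjusted over the list alone; the median log2 fold change was −0.37 (camera adjusted p = 0.00692, and adjusted p = 0.684 with an estimated correlation). The median was −0.15 without chow array 1 (adjusted p = 0.165), −0.44 without high-fat array 3 (0.0661) and −0.56 without chow array 3, and the list lost its call in the first 2 of these fits. After quantile normalization the median was −0.34 and the list was not called (adjusted p = 0.0568). Nor was it called with a normexp background (adjusted p = 0.549), where its median was −0.07 relative to all features. A different probe of Me1 showed 29.2% of its log2 change. Fasn, the fatty acid synthase, had a log2 fold change of 0.04 ± 0.44 (SE, adjusted p = 0.973), and Scd, the stearoyl-CoA desaturase, −0.95 ± 0.59 (SE, adjusted p = 0.414). Fasn turned to −0.19 with array weights, and was −0.47 without chow array 3 and 0.56 without chow array 1.

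Fatty acid breakdown and uptake genes were also lower as groups with 75th percentile scaling of the processed signal. These calls were lost after quantile normalization alone and with a normexp background alone. With a normexp background and quantile normalization together, mitochondrial oxidation and PPAR alpha targets were called lower (medians −0.23 and −0.26). The camera adjusted p in that setting was 0.0397 for both, and 0.593 for uptake (median −0.06). After quantile normalization the medians were −0.22 for mitochondrial oxidation (adjusted p = 0.126), −0.24 for PPAR alpha targets (0.0568) and −0.15 for uptake (0.652). Relative to all features the medians with a normexp background were 0.0008 for mitochondrial oxidation (adjusted p = 0.335), −0.20 for PPAR alpha targets (0.254) and 0.04 for uptake (0.895). Of 17 measured genes of mitochondrial fatty acid oxidation, 0 passed over all features and 7 fell when adjusted over the list alone, with a median of −0.41 (camera adjusted p = 0.000112, and adjusted p = 0.684 with an estimated correlation). Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, had a log2 fold change of −0.28 ± 0.21 (SE, adjusted p = 0.499). Targets of PPAR alpha and genes of peroxisomal oxidation had a median of −0.45 over 27 measured genes (camera adjusted p = 0.000112, and adjusted p = 0.684 with an estimated correlation). Of these 27 genes 0 fell and 1 rose, Cyp4a8, a fatty acid hydroxylase (log2 fold change 1.47 ± 0.24 SE, adjusted p = 0.0186); adjusted over the list alone, 1 rose and 1 fell. A different probe of Cyp4a8 showed 5.85% of the log2 change, and Cyp4a8 passed in 4 of 8 fits with single arrays left out and with a normexp background. Of 23 genes of fatty acid uptake and activation, 1 fell, Fabp2, a fatty acid-binding protein typical of intestine (2.06-fold lower, adjusted p = 0.0132), and 2 fell when adjusted over the list alone. The median of the uptake list was −0.26 (camera adjusted p = 0.025, and adjusted p = 0.684 with an estimated correlation). The call of this list was lost without high-fat array 5 (adjusted p = 0.0728), chow array 1 (0.0925) or chow array 2 (0.0688), and that of Fabp2 without chow array 1 and with a normexp background (adjusted p = 0.0628). Cd36, a fatty acid transporter, had a log2 fold change of 0.72 ± 0.30 (SE, adjusted p = 0.237). Ppara and Pparg, nuclear receptors that control lipid genes, had values of −0.39 ± 0.26 and 0.48 ± 0.37 (SE, adjusted p = 0.45 and 0.527).

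Amino acid breakdown had the smallest adjusted p of the 46 lists with camera at the preset correlation; after quantile normalization it was 0.0186, against 0.00875 for MHC class II. Of 28 measured genes of the urea cycle and amino acid catabolism, 3 fell, 0 rose, and 9 fell when adjusted over the list alone. Of the 28, 25 had negative values and the median was −0.44 (camera adjusted p = 2.02e-06, and adjusted p = 0.684 with an estimated correlation; fry adjusted p = 0.0391). The genes that fell were Gls2, the liver glutaminase (1.97-fold lower, adjusted p = 0.0216), Ass1, argininosuccinate synthase of the urea cycle (1.78-fold, 0.0351), and Gpt, alanine aminotransferase (2.01-fold, 0.0382). With single arrays left out Gls2 passed in 4 of 8 fits, and Ass1 and Gpt in 1. Gls2 also passed with a normexp background (adjusted p = 0.0357), and Ass1 and Gpt did not (0.114 and 0.129). Genes of MHC class II, which presents antigen to helper T cells, had a median of −0.49 over 10 measured genes (camera adjusted p = 0.00189, and adjusted p = 0.684 with an estimated correlation). RT1-Da, an alpha chain, fell 1.86-fold (adjusted p = 0.0445, lost when any 1 of the 8 arrays was left out), and 3 fell when adjusted over the list alone. RT1-Da also lost its call after quantile normalization (adjusted p = 0.0831) and with a normexp background (0.134). The labels give no rat strain, and MHC genes vary between strains.

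Glucose genes gave few calls. Of 18 measured genes of gluconeogenesis, 1 fell, Gpt, and 4 fell when adjusted over the list alone; the median was −0.25 (camera adjusted p = 0.00692, and adjusted p = 0.684 with an estimated correlation), and −0.38 without chow array 2. After quantile normalization the median was −0.21 and the list was not called (adjusted p = 0.258), nor was it with a normexp background (0.549; −0.03 relative to all features). The key enzymes did not pass: Pck1, which makes phosphoenolpyruvate, had a log2 fold change of 0.27 ± 0.21 (SE, adjusted p = 0.521) and G6pc1, which releases glucose, −0.15 ± 0.21 (SE, adjusted p = 0.746), with a positive value of 0.12 after quantile normalization. Glycogen metabolism was not called (17 genes, median 0.29, or 0.19 with 1 member at its lower bound, camera adjusted p = 0.335), but Ppp1r3b, which directs a phosphatase to glycogen, was 2.35-fold higher (adjusted p = 0.0405). Ppp1r3b passed in 1 of 8 fits with single arrays left out, and turned to −0.14 with a normexp background (0.15 relative to all features). Glycolysis was not called (22 genes, median −0.17, camera adjusted p = 0.288); Pklr, the liver pyruvate kinase, had a log2 fold change of 0.58 ± 0.32 (SE, adjusted p = 0.357). Slc2a2, the liver glucose transporter, had a value of −0.02 ± 0.24 (SE, adjusted p = 0.974), and 0.20 after quantile normalization.

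Insulin signalling was not called as a group (28 genes, 1 lower, Irs3, both over all features and over the list alone; median 0.03, mean −0.09, tested direction lower, camera adjusted p = 0.568). Insr, the insulin receptor, had a log2 fold change of 0.17 ± 0.20 (SE, adjusted p = 0.71), and Irs1 and Irs2, its main substrates in liver, had −0.14 ± 0.22 and −0.55 ± 0.42 (SE, adjusted p = 0.78 and 0.516). Insr turned to −0.04 with a normexp background (0.25 relative to all features), and Irs1 turned to 0.08 with a normexp background and quantile normalization.

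Cholesterol and bile acid genes were not called as groups. The 25 genes of cholesterol synthesis and uptake had a median of −0.09 (camera adjusted p = 0.451). Of 21 genes of bile acid synthesis and transport 1 rose, Hsd3b7, while the median was −0.22 (camera adjusted p = 0.202); adjusted over the list alone, 1 rose and 1 fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a value of 0.43 ± 0.49 (SE, adjusted p = 0.686), and −0.22 without chow array 2. Srebf1 and Acaca, named before the data were examined, were not analysed here.

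Liver function lists that were lower on high-fat diet without any member passing over all features were oxidative phosphorylation (40 genes, median −0.26, camera adjusted p = 0.000124), acute-phase proteins (24 genes, −0.31, 0.00162), hepatocyte markers (20 genes, −0.30, 0.00162) and lipoprotein assembly and clearance (27 genes, −0.25, 0.0158). Each had an adjusted p of 0.684 with an estimated correlation, and 0 members when adjusted over the list alone. After quantile normalization none of these 4 was called (adjusted p from 0.731 to 0.987): the medians were −0.05 for oxidative phosphorylation, −0.04 for acute-phase proteins, −0.06 for hepatocyte markers and −0.05 for lipoproteins. Relative to all features, the medians with a normexp background were 0.16, 0.05, 0.04 and 0.05, in the same order. The lipoprotein list lost its call without high-fat array 3 (adjusted p = 0.0712), high-fat array 5 (0.0542) or chow array 1 (0.0713) and had a median of −0.41 without chow array 2. Acute-phase proteins had a median of −0.19 without chow array 3, and hepatocyte markers −0.51 without chow array 2. Ribosomal proteins had a median of −0.24 over 42 genes (camera adjusted p = 0.000606, and adjusted p = 0.734 with an estimated correlation), which was −0.0046 after quantile normalization (adjusted p = 0.987), turned to 0.0045 in the authors' table, and was −0.37 without chow array 2 and −0.12 without chow array 3. Xenobiotic metabolism (41 genes, median −0.24, camera adjusted p = 0.0116) and sex-biased liver genes (22 genes, −0.26, 0.0133) each had an adjusted p of 0.684 with an estimated correlation. After quantile normalization they had medians of −0.01 and −0.03 (adjusted p = 0.893 and 0.987), and they turned to 0.0039 and 0.10 with a normexp background and quantile normalization. Without high-fat array 5 or chow array 3 neither was called (adjusted p = 0.0728 and 0.0559 for xenobiotic metabolism, with a median of −0.14 without chow array 3, and 0.0728 and 0.055 for sex-biased genes). Periportal hepatocyte markers, which include Gls2 and Ass1, had a median of −0.20 over 16 genes (camera adjusted p = 0.0133, and adjusted p = 0.684 with an estimated correlation). Of them 2 fell, and 4 fell when adjusted over the list alone; the median turned to 0.0066 after quantile normalization (adjusted p = 0.751). Their call was lost without high-fat array 3 (adjusted p = 0.0932), and the median was −0.44 without chow array 2.

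Skeletal muscle markers were the 1 list called higher, with a median that turned to −0.29 with a normexp background, equal to that of all features. Of 10 measured genes 2 rose, over all features and over the list alone, and the median was 0.50, or 0.05 with 4 members at their lower bounds (camera adjusted p = 0.0306, and adjusted p = 0.684 with an estimated correlation). Ckm, the muscle creatine kinase, was at least 3.31-fold higher (adjusted p = 0.0029), and Acta1, skeletal muscle actin, at least 1.43-fold higher (adjusted p = 0.0355); neither was above background on any chow array. The list lost its call without high-fat array 2 (adjusted p = 0.054), high-fat array 5 (0.0728) or chow array 2 (0.116), where its median was 0.38, 0.32 and 0.33, and after quantile normalization (median 0.28, adjusted p = 0.322). Ckm was 0.15 with a normexp background (adjusted p = 0.623), below the bound given above, or 0.44 relative to all features. Acta1 turned to −0.31 with a normexp background (−0.02 relative to all features) and passed in 2 of 8 fits with single arrays left out, and Ckm in 8. Of 13 pancreas markers 1 rose, Ins1, an insulin gene (at least 1.27-fold higher, adjusted p = 0.00469, and −0.30 with a normexp background, −0.01 relative to all features), and 2 rose when adjusted over the list alone. The pancreas median was 0.26, or 0 with 7 members at their lower bounds (camera adjusted p = 0.0985). In these lists the high-fat arrays of slide 1 lay below those of slide 2, by a median of −0.60 for muscle and −0.87 for pancreas.

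In total 16 of 46 lists were called by camera with a preset correlation, 15 lower and 1 higher, and 0 of these 16 were called with a normexp background (adjusted p from 0.252 to 0.895). With an estimated correlation 0 were called, and 1, amino acid catabolism, by fry, which tests whether the genes of a list move 1 way on balance and does not compare them with other genes. After quantile normalization, and in the authors' quantile-normalized table, 2 lists remained called, both lower: amino acid catabolism and MHC class II. Their adjusted p with a normexp background was 0.549 and 0.252, and relative to all features their medians in that setting were −0.0012 and −0.14. Of the 15 lists called lower, 5 had a median below that of all features with a normexp background and 10 above it. With the high-fat arrays of slide 1 alone, 12 lay below that of all features and 3 above, with 0 lists called. The mean of a list on each array did not overlap between diets for mitochondrial oxidation, gluconeogenesis, amino acid catabolism and MHC class II. It overlapped for the other lists called lower. For MHC class II the gap was narrow, with high-fat array 3 at 0.10 and chow array 3 at 0.14. The list means also did not overlap for skeletal muscle markers, called higher, or for glycogen metabolism and oxidative stress, which were not called. A lack of overlap is therefore not particular to the lists called lower.

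**Figure D4:**
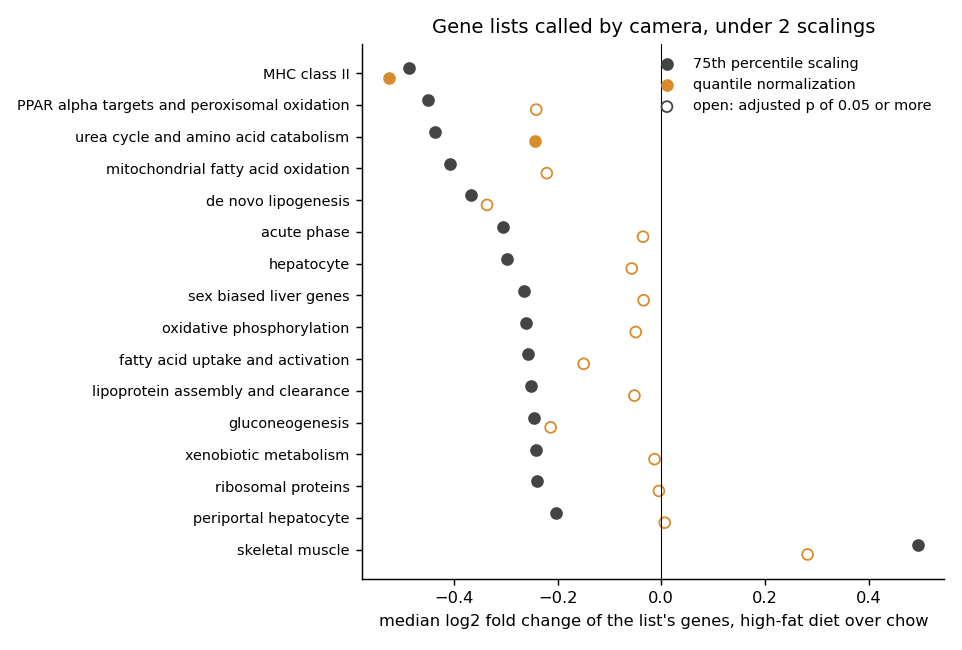
Median log2 fold change, high-fat diet over chow (x axis), of the genes in each of the 16 lists called by camera (y axis), with 75th percentile scaling (grey) and after quantile normalization (orange); filled points have an adjusted p under 0.05 in that setting. With quantile normalization 2 of the 16 keep a filled point, the periportal list turns from −0.20 to 0.0066, and the other 15 keep their sign.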

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

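The rule that picks out a sample far from the rest of its group was fixed before the data were examined, and no test of an explanation was run for the 2 genes it picked out. In 84 results tested for the high-fat group of 5, an array stood apart if its gap to the nearest other array was over 0.71 of the group's range. Chance alone picks out about 1 in 20, and groups of 3, such as chow, were not tested. Fam13a, called lower on high-fat diet, was −3.80 on high-fat array 3 and −5.28 to −4.89 on the other high-fat arrays; without array 3 its log2 fold change was −1.79 (adjusted p = 0.00627). Ppp1r3b, called higher, was −3.99 on the same array and −3.35 to −3.15 on the others; without array 3 its log2 fold change was 1.39 (adjusted p = 0.0232). Both genes remained called without array 3, and no biological explanation was tested. The adjusted p ran from 0.006 to 0.531 over 26 alternatives for Fam13a and from 0.013 to 0.724 over 25 for Ppp1r3b.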

How the results depend on the processing

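Cyclic loess, the arrays of scan day 1 alone, the high-fat arrays of slide 1 alone, and the alternatives for single lists other than the estimated correlation and fry, and all those for the separation of arrays, were chosen after seeing the data. Against 815 features, the count called was 148 with a normexp background, 2110 with a normexp background and quantile normalization, 486 with a filter on all 8 arrays, 3774 with array weights, 84 with slide as a random block, 3717 with scan day as a block, 1249 with cyclic loess, 2904 on scan day 1 alone, 1979 with the high-fat arrays of slide 1 alone, and 1300 at an unadjusted p under 0.05 with at least 2-fold change. The replicate block on the 6 arrays numbered 1 to 3 gave 0 in limma (3072 at an unadjusted p under 0.05), and the same arrays without the replicate block gave 317. The same-number correlations of residuals were 0.083, −0.0044 and 0.059, and the others ran from −0.077 to 0.040. So few correlations cannot settle whether the numbers pair the samples. Against 624 features with at least 2-fold change, the same settings gave 124, 253, 286, 1504, 84 and 1763, then 1710 on scan day 1 alone, 1488 on slide 1 alone, 0 with the replicate block and 317 without it; cyclic loess kept the count within 1.5 times. The fewer arrays or genes of the filtered and subset settings are part of their construction. For the other settings the cause was not tested.

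Of 703 features called higher, 543 remained with quantile normalization, 129 with a normexp background, 418 with a normexp background and quantile normalization, and 84 with slide as a random block; of 112 called lower, 82, 13, 95 and 0 remained. The direction of the calls also moved: 699 higher and 396 lower without a filter on dim probes, 2195 and 1579 with array weights, 1035 and 1075 with a normexp background and quantile normalization, and 998 and 981 with the high-fat arrays of slide 1 alone. Against 16 lists, 2 were called with quantile normalization, 2 in the authors' table, 2 with cyclic loess, 2 with a normexp background (both higher, neither among the 16) and 2 with a normexp background and quantile normalization, 0 with the high-fat arrays of slide 1 alone, 0 with an estimated correlation, and 1 with fry. The 2 called with a normexp background and quantile normalization were mitochondrial fatty acid oxidation and PPAR alpha targets, both lower. The correlation within groups exceeded that between groups by 0.00731, and by 0.0146 with the high-fat arrays of slide 1 alone. No pair of arrays from different diets shared a slide. High-fat arrays of different slides correlated at 0.971 to 0.979, against 0.967 to 0.978 between high-fat and chow arrays. This excess therefore does not separate diet from slide. The median of all features was −0.01, −0.08 with median scaling, −0.13 with the high-fat arrays of slide 1 alone and −0.29 with a normexp background. With that background, 10 of the 15 lists called lower had a median above that of all features. With the high-fat arrays of slide 1 alone, 3 of the 15 did.

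Leaving out 1 array at a time gave 374 to 789 features, 369 to 676 with at least 2-fold change, and 11 to 18 lists, and an overall separation of arrays (the difference in correlation) of 0.00623 to 0.00819. The counts left 1.5 times the full count without chow array 1 (374), 2 (440) or 3 (432) and without high-fat array 2 (455), and at 2-fold without chow array 1 (369), 2 (395) or 3 (412). With single arrays left out Fasn ran from −0.47 to 0.56, Cyp7a1 from −0.22 to 0.84 and Slc2a2 from −0.11 to 0.15. Of the named genes that passed, Gclm, Ltb4r2, Msx3, Id3, Arvcf, Prim2, Ins1, Ckm, RT1-CE11 and RT1-CE4 passed in all 8 of these fits, the others in fewer, and Acacb and RT1-Da in 0. The called lists passed in all 8 except lipogenesis, xenobiotic metabolism and sex-biased genes (6), lipoproteins, fatty acid uptake and skeletal muscle (5), and the periportal list (7).

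Some values changed sign, none of them past the threshold after the change, and the cause was not tested. With a normexp background Brd1 was −0.20, Ltb4r2 −0.029, Ppp1r3b −0.14, Pdgfb −0.62, Ins1 −0.30, Acta1 −0.31, the skeletal muscle list −0.29, G6pc1 0.0040, Slc2a2 0.12 and Insr −0.042; relative to the median of all features in that setting, Brd1 was 0.09, Ltb4r2 0.26, Ppp1r3b 0.15, Pdgfb −0.33, Ins1 −0.01, Acta1 −0.02, the skeletal muscle list −0.0038, G6pc1 0.29, Slc2a2 0.41 and Insr 0.25. With a normexp background and quantile normalization G6pc1 was 0.16, Slc2a2 0.24, Irs1 0.081, xenobiotic metabolism 0.0039 and sex-biased liver genes 0.10. With quantile normalization G6pc1 was 0.12, Slc2a2 0.20 and the periportal list 0.0066. In the authors' table G6pc1 was 0.12, Slc2a2 0.20, the periportal list 0.0075 and ribosomal proteins 0.0045. With cyclic loess G6pc1 was 0.13, Slc2a2 0.25, the periportal list 0.0040 and ribosomal proteins 0.013. With slide as a random block Slc2a2 was 0.013. With the high-fat arrays of slide 1 alone G6pc1 was 0.024, Slc2a2 0.29 and Insr −0.058 (0.16, 0.43 and 0.07 relative to all features). Fasn was −0.034 with median scaling, which lowers every feature by 0.0757, −0.19 with array weights, and −0.072 both with scan day as a block and on scan day 1 alone. Irs1 was 0.14 with the mean over probes, 0.01 with array weights, 0.075 both with scan day as a block and on scan day 1 alone, and 0.023 on the 6 arrays numbered 1 to 3 with and without the replicate block.

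Of the genes named, Gclm passed in 23 of 25 alternatives, Id3 in 25 of 26, Prim2 in 24 of 26 and Fabp2 in 21 of 26, while RT1-Da passed in 10, Gpt in 12 and Acacb in 12 of 26. The amino acid list was called in 24 of 28 alternatives and the MHC class II list in 23 of 28. Genes near the background of the chow arrays have a fold limited by that background. The normexp settings also replaced the processed signal by the median spot signal and added an offset of 50 before the log. The effects of the background model, the signal and the offset were not separated. The median processed signal was 39.1 to 72.5 intensity units on the chow arrays and 84.2 to 179 on the high-fat arrays. The same offset is therefore larger relative to the signals of the chow arrays, and dim genes can lose their change through it.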

Other observations

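The genes of this paragraph were chosen after their values were seen and were not tested as a list. Nnmt, which methylates nicotinamide, was 2.05-fold lower (log2 fold change −1.04 ± 0.20 SE, limma adjusted p = 0.0282), Naprt, which starts NAD synthesis from nicotinic acid, 1.80-fold lower (adjusted p = 0.0237), and Slc13a5, a citrate importer, 1.98-fold lower (adjusted p = 0.0281). Ido1, which opens the tryptophan ring on the way to kynurenine, was 1.92-fold lower (adjusted p = 0.035), Kyat1, a kynurenine aminotransferase, 1.74-fold lower (adjusted p = 0.0335), and Agxt, which clears glyoxylate, 1.78-fold lower (adjusted p = 0.0278). The MHC class I genes RT1-CE11 and RT1-CE4 were 3.14-fold and 2.45-fold higher (adjusted p = 0.00167 and 0.00379), and Txnip, a glucose-responsive regulator of thioredoxin, was 3.02-fold higher (adjusted p = 0.0132). Cyp4a1, a fatty acid hydroxylase, and Sds, serine dehydratase of amino acid breakdown, had log2 fold changes of −1.04 ± 0.25 and −1.86 ± 0.47 (SE) and did not pass (adjusted p = 0.0622 and 0.0736). With single arrays left out RT1-CE11 and RT1-CE4 passed in 8 of 8 fits, Txnip in 6, Nnmt and Naprt in 4, Slc13a5 and Agxt in 2, and Ido1 and Kyat1 in 1. RT1-CE11, RT1-CE4 and Txnip passed with a normexp background, and the other 6 did not (adjusted p from 0.0715 to 0.2). The labels give no rat strain, and MHC class I genes vary between strains, so a strain difference between the groups was not excluded. The groups did not overlap for any of the 9 genes that passed, which the threshold on p selects for and which adds no support.

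In the 30 lists that were not called (camera adjusted p from 0.0985 to 0.984), single members passed. Bhlhe40, a repressor of the circadian clock, rose 3.24-fold (adjusted p = 0.0405), Zfp36, which speeds decay of messenger RNA, 3.28-fold (adjusted p = 0.0389), and Pdgfb, a growth factor for stellate cells, at least 1.28-fold (adjusted p = 0.0413, −0.62 with a normexp background, −0.33 relative to all features; a different probe showed 33.9% of its log2 change). Each of these 3 passed in 2 of 8 fits with single arrays left out, and none with a normexp background (adjusted p from 0.114 to 0.247). Adjusted over the list alone, 1 circadian gene rose and 1 fell, 1 immediate-early gene, 1 cholangiocyte marker and 1 matrix gene rose, 2 pericentral genes rose, 2 pentose phosphate genes and 1 adipokine receptor gene fell, and in oxidative stress 1 rose (Gclm) and 1 fell (Me1). Median log2 fold changes were 0.12 for the circadian clock, −0.24 for immediate-early and heat shock genes, −0.11 for cholangiocytes, −0.18 for matrix and fibrosis, −0.20 for pericentral hepatocytes, −0.07 for the pentose phosphate pathway, −0.10 for adipokine and glucagon receptors and −0.0012 for oxidative stress (tested direction higher). No member passed, over all features or over the list alone, in ketogenesis (0.13), triglyceride synthesis (−0.10), fructose and sugar transport (−0.12), ER stress (0.14), interferon response (−0.03), cell cycle (0.16, or 0.06 with 1 member at its lower bound), transcription factors of lipid and glucose genes (0.01, mean −0.02, tested direction lower) or chemokines and cytokines (0.02, also with 2 members at their bounds, mean 0.04, tested direction lower). The same held for markers of Kupffer cells and macrophages (−0.18), T and NK cells (0.04, or 0 with 2 members at their bounds), B and plasma cells (−0.06, also with 1 member at its bound), neutrophils and mast cells (0.37, or 0.23 with 2 members at their bounds), stellate cells (−0.02, or −0.07 with 2 members at their bounds), endothelium (−0.11, mean 0.03, tested direction lower), red blood cells (−0.19) and adipose tissue (−0.09, mean 0.15, tested direction higher).

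The counts of splits were planned before the data were examined, while the comparison of slides and the tests of slide, probes, scaling and control probes were chosen after the results were seen. Within the high-fat group, 6404 of 22863 tested features were called between the 2 arrays of slide 1 and the 3 arrays of slide 2 (1310 higher and 5094 lower on slide 1). Of the 815 features called between diets, 113 were among them, a smaller share than that of all features. A call between diets selects for a small spread within the high-fat group, so this share says nothing for or against slide. Of the 56 splits of the 8 arrays into 5 and 3, 2 gave at least 815 called features, the real one included. This argues against chance only for arrays taken without regard to slide. The other, with 1917 features, set high-fat arrays 2, 3 and 5 against the rest; that is slide 2, so the count points to a structure of the samples by slide, and with slide as a random block 84 features passed. The same 2 splits gave at least the 624 features with 2-fold change (highest other 1145). For the 16 lists called, 15 of the 56 splits gave as many (highest other 23), so chance is not excluded.

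The first pattern is the 703 features called higher on high-fat diet, many of them dim. A difference in brightness distribution alone was argued against by quantile normalization, after which 77.2% of these features stayed called. Slide stays open: with slide as a random block 11.9% stayed called. Their median log2 change was 1.465 before and 1.467 after, and its SE rose from 0.224 to 0.343, so the calls ended through the wider error. Chow shares its slide with no high-fat array, so this block could not take a slide effect out of the change. The steady median therefore says nothing for or against slide. Probe-specific signal also stays open: over 19 genes a different probe showed a median of 25.9% of the change (9 under 25% and 6 over 50%). Nonspecific hybridization of the high-fat arrays stays open as well: the E1A control probes differed by −0.42 (high-fat minus chow, relative to the 75th percentile), which did not pass (exact permutation p = 0.196), and on the chow arrays they lay at −6.35 to −5.93, under the lowest signal above background (−5.09 to −4.55). So does the handling of background, since 129 of the 703 remained with a normexp background (148 called in all) and 418 with that background and quantile normalization. Diet, which the design names, cannot be told apart from slide.

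The second pattern is the 112 features called lower. A difference in brightness distribution alone was argued against, since 73.2% stayed called after quantile normalization. Slide stays open, as 0% stayed called with slide as a random block. The median log2 change was −0.83 before and after, and its SE rose from 0.161 to 0.266. Here too the block could not take a slide effect out of the change. A different probe showed a median of 50.6% of the change in 19 genes (6 under 25% and 10 over 50%), so signal of single probes stays open too. Diet may explain these genes, but it cannot be told apart from slide.

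The third pattern is the 15 lists called lower. For most of them the brightness of their genes is a candidate explanation: 2 of the 15 stayed called lower after quantile normalization. The larger camera adjusted p of those 2, amino acid catabolism and MHC class II, was 0.0186 after quantile normalization. They were picked out because they stayed called there, so this is no separate test of brightness for them. Over the alternatives the adjusted p ran from 2.66e-07 to 0.684 for amino acid catabolism and from 0.000547 to 0.684 for MHC class II. Neither of these lists passed with a normexp background (0.549 and 0.252) or with that background and quantile normalization (0.0967 and 0.166). In the latter setting mitochondrial fatty acid oxidation and PPAR alpha targets were called lower (camera adjusted p = 0.0397 for both). Relative to all features, the median with a normexp background was −0.0012 for amino acid catabolism, so its decrease was not seen there, and −0.14 for MHC class II. With that background and quantile normalization the medians of these 2 lists were −0.19 and −0.25, against 0.003 over all features. Background handling stays open for both of them. For MHC class II a strain difference also stays open, as the labels give no strain. A lower expression of these genes in fatty liver is a hypothesis that slide and correlation between genes leave open.

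A few choices of tests changed after results were seen. A first test of slide compared the median difference between the high-fat slides with 10000 random sets of equal brightness: it was 0.01 for the features called higher (95% of random sets from −0.40 to −0.28) and −0.02 for those called lower (−0.03 to 0.13). It was replaced because a gene is called when its spread within the high-fat group is small, which fixes that outcome. The bounds for the probe test were tightened after the shares of 25.9% and 50.6% were seen; under the earlier bounds the share of 50.6% would have counted against probe-specific signal for the features called lower. The bound for the control probes was tightened after their difference of −0.42 was seen; under the earlier bound it would have counted against nonspecific hybridization.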
